A study of Homo sapiens with 7 samples.

How the data were processed

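The deposited table holds 1 union set of 29885 ER sites on GRCh38 for 6 ER libraries, with a signal column and a call per library. The signal values are normalised read counts per site as deposited by the authors, and the calls (other) are 0 or 1 flags of a called peak, also deposited by the authors. Per the submitters' processing notes GSNAP, MACS2 2.1.0 and GRCh38 were used, with no role given for each here. Per the labels an input sample exists for all ER libraries, and a Drosophila chromatin spike-in is named in the protocol. Division of each library by its smallest step recovered whole reads for 100% of the values at a tolerance of 1e-06, and the size factors found in this way were 0.987 for Vehicle, 0.925 for E2, 1.24 for fulvestrant, 1.05 for 4OH-tamoxifen, 0.909 for GDC-0927 and 0.851 for GNE-274. The basis of the size factor is not given in the sources used here. In the table, 1 flag column belonged to none of the samples and was left out, and the input sample has no column. The sites were 200 to 824 bases wide with a median of 231, and 99.97% of the 10751 sites called in 1 library had the minimum width.

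Log2 ratios used a pseudocount of 1, and a site counted as higher or lower at a limit of 2-fold. Folds are ratios of normalised values without pseudocount, with an exact 95% interval from the reads of the 2 libraries given their size factors. The two-sided exact binomial test on reads with Benjamini-Hochberg adjustment over the 29885 sites called sites at an adjusted p of 0.05, and was added after seeing the data. A value relative to the shift is the log2 ratio minus the median of all sites in that comparison. A gene was represented by its site of highest mean value among sites with its symbol in the deposited annotation, and 90.8% of sites had a symbol matched to the RefSeq table. No distance limit was set, so a site given under a gene need not lie near it or act on it. Location classes are those deposited by the authors.

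The 12 gene lists (estrogen-induced, estrogen-repressed, luminal transcription factors, cell cycle, AP-1 and immediate early, nuclear receptor coregulators, aryl hydrocarbon receptor response, basal and mesenchymal, liver, T cell, neural and housekeeping) were fixed in advance. The median of a list was placed among 10000 random lists of the same size matched on decile of mean value, and percentiles outside the central 95% were counted. The random lists were not matched on location class, so the share of promoter sites in a list can move its percentile. Genes were named by a rule: the 20 estrogen-induced genes and the 4 genes of each other list with the highest mean value, the 10 highest and 10 lowest sites per comparison among sites above the median mean value, and the 10 sites of highest mean value. The read test and intervals were tested on simulated data with sites of known fold, where 0 to 5 unchanged sites of 29885 were called and intervals covered the truth for 96.2 to 96.5% of unchanged sites. Of changed sites, 94 to 100% were called at 4 times the value but 42 to 64% at 0.25 times, and 28 to 42% at 2 times but 14 to 30% at 0.5 times, so the test missed more lower than higher sites.

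Alternatives were scaling to equal medians, scaling to equal totals, pseudocounts of 0.1 and 5, a limit of 1.5-fold, sites above the median mean value alone, leaving out chromosomes 1, 17 and 20, the mean of all sites per gene, and, added after seeing the data, leaving out promoter sites, gene lists within 10 kb of the gene body and the binomial test. The sharing of 1 Vehicle library was examined with 20 simulations without effect. Motif content and distance to transcription starts were left out, because no reference genome came with the series and the gene table has no strand. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.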

Results

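Genome-wide binding of estrogen receptor alpha (ER), the nuclear receptor that carries the transcriptional response to estrogen, was measured by ChIP-seq in MCF-7, an estrogen-dependent human breast cancer cell line. Cells kept without hormone received the DMSO vehicle, 1 nM estradiol (E2, the natural agonist) or 100 nM of 1 of 4 test compounds for 45 min. Fulvestrant is an ER antagonist that also promotes degradation of the receptor, and 4OH-tamoxifen is the active metabolite of tamoxifen, an ER antagonist in breast cells. GDC-0927 and GNE-274 are ER ligands given here by their code names, and the sample used as GNE-274 carries that name in its ligand label but a differently spelled code in its title. The question set by the design was how ER occupancy after 45 min differed between these 5 ligands and the vehicle. Each of the 6 conditions had 1 ER library, so no spread between cultures was measured and no test between conditions was possible. Reads within the 29885 sites numbered 687472 for Vehicle, 2336964 for E2, 1675127 for fulvestrant, 1986117 for 4OH-tamoxifen, 1403798 for GDC-0927 and 2371149 for GNE-274. Folds are ratios of normalised read counts with exact 95% intervals from the reads, which cover counting error only. Intervals of shares and odds ratios are over sites. In the closing section, intervals other than those of folds came from resampling sites with replacement (bootstrap). Sites are not replicates, so no interval covers the spread between cultures.

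ER sites were higher and more numerous after every ligand than in Vehicle on the deposited scale. The median normalised read count per site was 12.2 in Vehicle, 23.3 after fulvestrant, 26.4 after GDC-0927, 33.3 after 4OH-tamoxifen, 37.8 after E2 and 48.2 after GNE-274. The authors called 4413 sites in Vehicle, which was 14.8% (14.4 to 15.2, exact binomial) of the union, against 16114 sites or 53.9% (53.4 to 54.5) with E2. Fulvestrant had 12712 called sites, GDC-0927 had 12182, 4OH-tamoxifen had 16287 and GNE-274 had 22517. A set of 5724 sites was called with all 5 ligands and not in Vehicle, and 5111 sites were called with GNE-274 alone. Called in Vehicle alone were 1551 sites, of which 61.6% lay in promoters, against 6.83% of the sites called with all 5 ligands and not in Vehicle. The levels between libraries rest on deposited size factors of unstated basis, and with equal totals the 6 medians lay between 24.5 and 28.9. Scaling to equal totals or equal medians removes any gain common to all sites by construction. It therefore cannot tell a true common gain from a technical one. Because the basis is unstated, some ratios at single sites are also given relative to the shift, and those without such a value are on the deposited scale alone. The shift is the median log2 ratio over all sites of the same comparison.

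**Figure D1:**
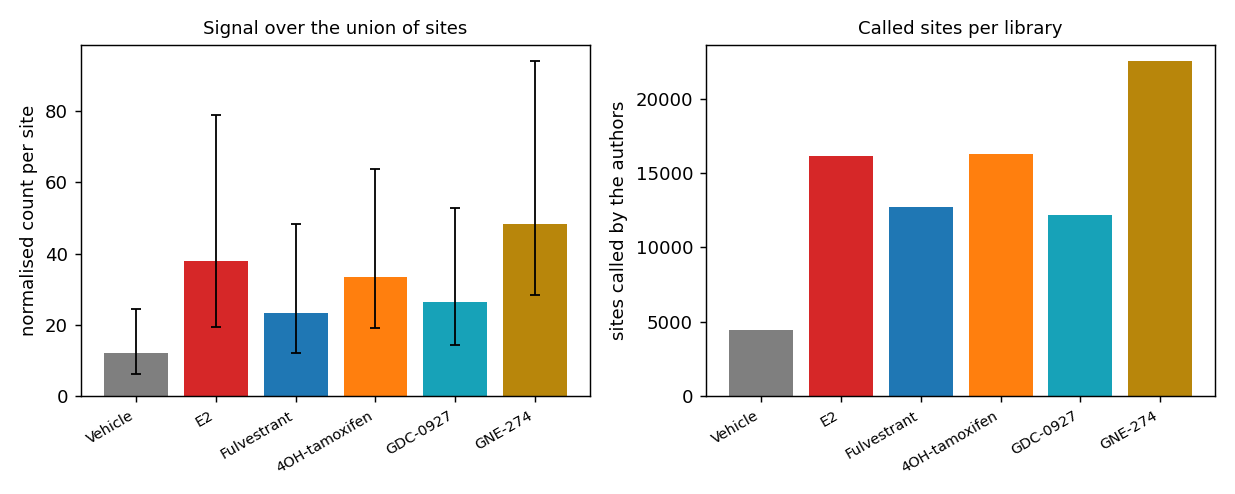
Left, median normalised read count over the 29885 sites per library (bars) with quartiles (whiskers); right, number of sites the authors called per library. The medians run from 12.2 in Vehicle to 48.2 with GNE-274 on the deposited scale, and with equal totals they lay between 24.5 and 28.9 with no such order. Equal totals remove a gain common to all sites by construction.

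The comparison of E2 with Vehicle asked where the agonist placed the receptor. At the site assigned to TFF1, a secreted trefoil protein and classical estrogen target, E2 was 9.64 (8.51 to 10.9) times Vehicle (chromosome 21, 42376348 to 42376606, intron of TMPRSS3). The promoter site of GREB1, a coactivator induced by estrogen, was 5.92 (5.11 to 6.89) times Vehicle (chromosome 2, 11539528 to 11539816), and the promoter site of PDZK1, a scaffold protein, was 24.4 (18.9 to 31.9) times Vehicle (chromosome 1, 145708196 to 145708471). RET, a receptor tyrosine kinase, had an intronic site at 28.9 (18.9 to 46.5) times Vehicle (chromosome 10, 43110793 to 43111049). IGFBP4, which binds insulin-like growth factors, had an intronic site at 11.5 (9.51 to 14.0) times Vehicle (chromosome 17, 40448706 to 40448961), while RARA, a retinoic acid receptor, had a promoter site at 3.77 (3.33 to 4.28) times Vehicle (chromosome 17, 40322357 to 40322587). Over all sites the median log2 ratio was 1.71, which is the shift, and 21044 sites were at least 2-fold higher and 1237 at least 2-fold lower. With each library scaled to an equal median the split was 7822 higher and 5895 lower, and with equal totals the median turned to -0.02. Relative to the shift, PDZK1 stood at 2.88, RET at 3.08, IGFBP4 at 1.80, TFF1 at 1.55, GREB1 at 0.85 and RARA at 0.20 on the log2 scale. The exact binomial read test, which compares the 2 libraries and not the conditions, called 20108 sites higher and 1490 lower.

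Among the estrogen-induced genes, 32 of 34 had a site, and 30 of these were at least 2-fold higher with E2 at their strongest site, with a median log2 ratio of 3.06. That median lay at the 98.6 percentile of 10000 random gene lists matched on signal, and 27 of the 32 genes stood above the shift. The random lists had a median of 2.54, also above the shift of 1.71, so a place above the shift is not particular to this list. MYC, a growth-promoting transcription factor, was a member with lower values at its promoter, 78.9 with E2 against 107 in Vehicle (chromosome 8, 127736251 to 127736613), and stood at -2.15 relative to the shift. The estrogen-repressed genes (10 of 10 with a site) had a median of 0.80, at the 2.35 percentile. Within this list NEDD9, a focal adhesion scaffold, was 12.9 (6.31 to 30.8) times Vehicle (chromosome 6, 11390036 to 11390256, intergenic), whereas EFNA1, an ephrin ligand, had 163 against 108 at its promoter (chromosome 1, 155127038 to 155127664), higher on the deposited scale and -1.13 relative to the shift. Of the luminal transcription factors, 11 of 12 were at least 2-fold higher with E2, with a median of 2.84 at the 85.2 percentile. Examples were GRHL2, an epithelial regulator, at 19.5 (15.6 to 24.6) times Vehicle (chromosome 8, 101466723 to 101466957, intron of GRHL2-DT), ESR1, which encodes ER itself, at 9.11 (7.46 to 11.2) (chromosome 6, 151616211 to 151616428, intron of CCDC170), and TFAP2C at 7.67 (6.87 to 8.59) (chromosome 20, 56735308 to 56735552, intergenic). The cell cycle genes (10 of 16 with a site) had a median of 0.31, at the 1.53 percentile, although CDK1, the mitotic kinase, had an intergenic site at 14.6 (10.3 to 21.2) times Vehicle (chromosome 10, 60848707 to 60848954). Promoter sites as a class had a median of 0.20 with E2, and the random lists were not matched on location. The estrogen-induced list shares 6 genes with other lists, namely MYC, CCND1, NRIP1, EGR3, MYB and XBP1, and a percentile describes these libraries alone. Within 10 kb of the gene body the cell cycle and estrogen-repressed percentiles moved to 7.99 and 9.15, and with the mean of all sites per gene the estrogen-induced percentile moved to 95.7.

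The test compounds were then set against Vehicle, to ask which sites were occupied when the receptor was bound by each of them. TFF1 was 1.31 (1.13 to 1.53) times Vehicle with fulvestrant, 2.31 (2.001 to 2.67) times Vehicle with GDC-0927, 2.97 (2.59 to 3.41) with 4OH-tamoxifen and 6.68 (5.88 to 7.62) with GNE-274. GREB1 followed with 1.40 (1.18 to 1.67), 2.63 (2.23 to 3.10), 4.97 (4.28 to 5.78) and 7.003 (6.05 to 8.14) times Vehicle in the same order. IGFBP4 was higher with every test compound, from 4.88 (4.009 to 5.98) times Vehicle with fulvestrant to 17.01 (14.1 to 20.7) with GNE-274. CTSD, a lysosomal protease, was 4.59 (3.901 to 5.43) times Vehicle with fulvestrant and 7.502 (6.38 to 8.87) with GNE-274 (chromosome 11, 1796617 to 1796854, intergenic). Relative to the shift of each comparison, TFF1 and GREB1 turned to -0.72 and -0.62 with fulvestrant, and TFF1 to -0.05 with 4OH-tamoxifen and -0.02 with GDC-0927, so these directions depended on the scale. On the same measure IGFBP4 stood between 1.17 and 1.91 and CTSD between 0.72 and 1.25 with the 4 compounds. The estrogen-induced genes had a median log2 ratio of 1.14 with fulvestrant (percentile 4.59), 1.98 with GDC-0927 (87.5), 2.49 with 4OH-tamoxifen (96.2) and 2.95 with GNE-274 (88.6). Relative to the shift these medians were 0.04, 0.76, 0.87 and 0.77. GNE-274 had a low percentile for the cell cycle genes, 1.40, which moved to 7.43 within 10 kb of the gene body.

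The shift against Vehicle was 1.11 with fulvestrant, 1.23 with GDC-0927, 1.62 with 4OH-tamoxifen and 2.18 with GNE-274. Sites at least 2-fold higher and lower numbered 16220 and 2145 with fulvestrant, 17491 and 1698 with GDC-0927, 20684 and 1787 with 4OH-tamoxifen and 23563 and 1088 with GNE-274. After scaling to equal medians the splits were 6712 and 4822, 6555 and 4726, 7633 and 5503, and 8278 and 5868 in the same order. The exact binomial read test called 14402 sites higher and 2449 lower with fulvestrant, 15338 and 1832 with GDC-0927, 20044 and 2093 with 4OH-tamoxifen and 23835 and 1307 with GNE-274.

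**Figure D2:**
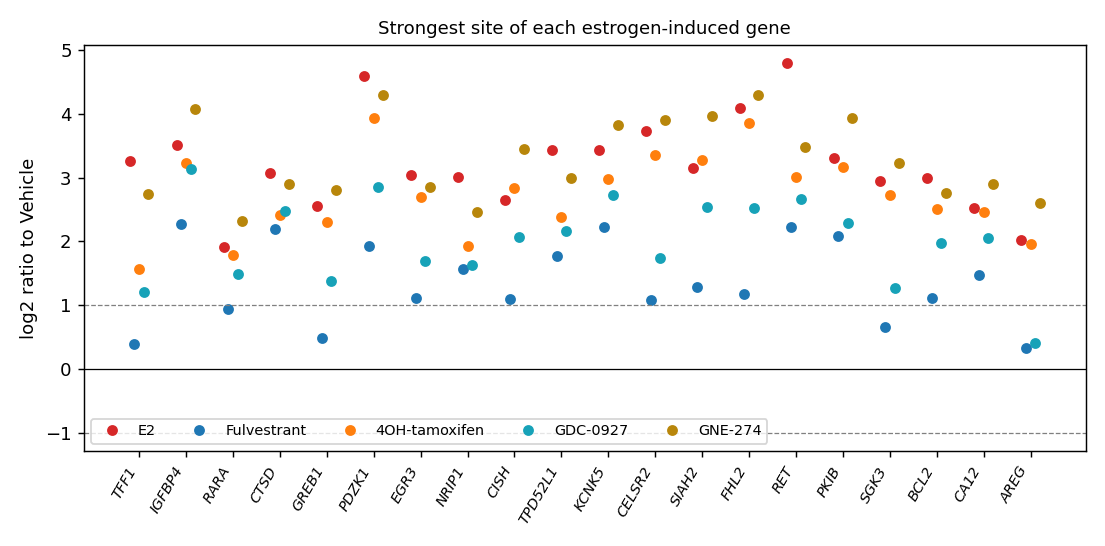
Log2 ratio to Vehicle (y) at the strongest site of the 20 named estrogen-induced genes (x), with 1 point per ligand. E2 reached a log2 ratio relative to the shift of 3.08 at RET, and fulvestrant points at TFF1 and GREB1 lie above 0 but turn to -0.72 and -0.62 relative to the shift.

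Sites higher or lower with all 5 ligands were counted with the caveat that every ratio shares the single Vehicle library. At least 2-fold higher with all 5 ligands were 12447 sites, where independent lists of these sizes would share 3648 and 20 simulations without any effect gave at most 45. At least 2-fold lower with all 5 were 682 sites, against 0.011 for independent lists and at most 3 in the simulations, and after scaling to equal medians the counts were 2613 higher and 2812 lower. The simulations gave all 6 libraries the same level per site with counting error alone. They held no shift between libraries and no library error, so they cannot separate a ligand effect from either. Promoters made up 60.9% of the sites lower with all 5 ligands and 4.60% of those higher with all 5. All 682 sites lower with every ligand were sites the authors called in Vehicle. Each site of the union was called in at least 1 library, so this is largely set by how the sites were listed. Of all sites called in Vehicle, 48.5% were promoters. The median correlation between the 5 ratios was 0.7996, against 0.498 in the simulations, and a single Vehicle library cannot be split to remove the shared part.

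The location of the sites was compared to ask whether promoters and other sites had like ratios. The promoter of STK25, a Golgi-linked kinase, had a normalised count of 227 in Vehicle and 32.4 with E2, a ratio of 0.143 (0.0942 to 0.210) (chromosome 2, 241508628 to 241508849). The promoter of NCOA3, an ER coactivator amplified in breast cancer, was 0.241 (0.207 to 0.279) times Vehicle with E2 and 0.0930 (0.0746 to 0.115) times with 4OH-tamoxifen (chromosome 20, 47501734 to 47501949), whereas the strongest site of this gene, intergenic, was 2.87 (2.41 to 3.43) and 2.92 (2.46 to 3.49) times Vehicle, or -0.20 and -0.08 relative to the shift (chromosome 20, 47464484 to 47464722). PSMD6, a proteasome subunit, had a promoter site at 0.177 (0.132 to 0.233) times Vehicle with E2 (chromosome 3, 64023300 to 64023499). Among sites above the median mean value, 7 of the 10 lowest E2 ratios and 10 of the 10 lowest 4OH-tamoxifen ratios were promoters, while 0 of the 10 highest E2 ratios were. The same count among the 10 lowest ratios was 7 with fulvestrant, 5 with GNE-274 and 4 with GDC-0927. The 10 highest E2 ratios included intronic sites of PRLR, the prolactin receptor, with 1.01 in Vehicle and 149 with E2 (chromosome 5, 35205657 to 35205916), and of FOXP1, a forkhead factor, with 0 in Vehicle and 60.5 with E2 (chromosome 3, 71384468 to 71384676). These Vehicle values are a single read, worth 1.01, and none. Promoter sites had a Vehicle median of 31.4 against 10.1 at other sites, so the count of 0 promoters may in part reflect the Vehicle level. Promoters held 14.6% of all sites, and their median log2 ratio to Vehicle was 0.20 with E2 against 1.88 at other sites, 0.35 against 2.35 with GNE-274 and -0.31 against 1.22 with fulvestrant. With 4OH-tamoxifen the pair was -0.02 and 1.77, and with GDC-0927 it was 0.04 and 1.33. The 2212 promoter sites not called in Vehicle had higher medians, 1.037 with E2, 0.576 with fulvestrant and 0.833 with 4OH-tamoxifen. With GDC-0927 and GNE-274 their medians were 0.803 and 1.199. The negative promoter medians with fulvestrant and 4OH-tamoxifen thus depended on sites called in Vehicle, while all 5 medians without them stayed below the shift. At least 2-fold higher with E2 were 29.2% of promoter sites and 77.4% of other sites, an odds ratio of 0.120 (0.112 to 0.129) in a two-sided Fisher exact test over sites of these libraries. The odds ratios with the other ligands ran from 0.0729 (0.0678 to 0.0785) with GNE-274 to 0.176 (0.164 to 0.190) with GDC-0927. The median promoter ratio was below the shift with every ligand. Low medians were not particular to promoters. In the order E2, fulvestrant, 4OH-tamoxifen, GDC-0927 and GNE-274, the 437 sites in 5' UTRs had medians of -0.21, -0.84, -0.62, -0.45 and -0.20. The 115 coding sites had 0.02, -0.43, -0.46, -0.36 and -0.32. Intron, intergenic and 3' UTR sites had medians of 1.86, 1.94 and 1.57 with E2.

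**Figure D3:**
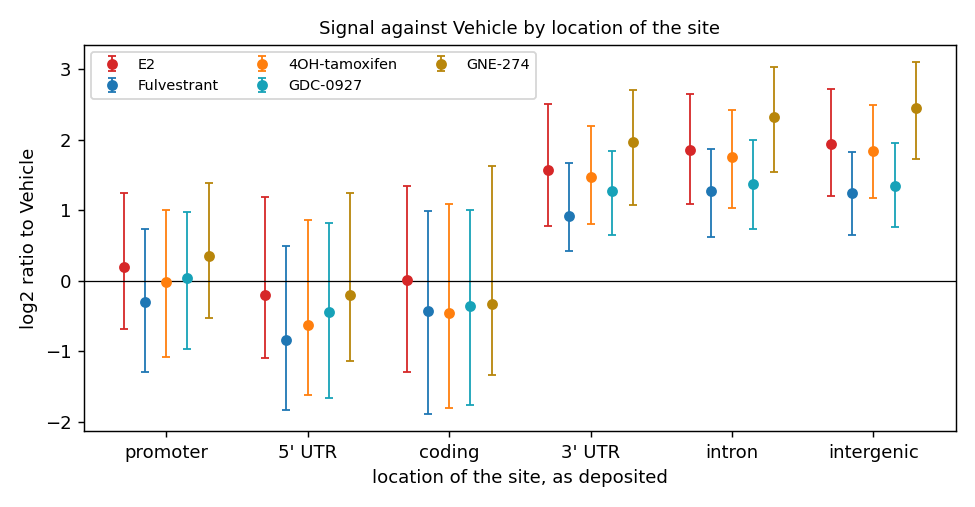
Median log2 ratio to Vehicle (points) and quartiles (bars) by deposited location class of the site, for each of the 5 ligands. Promoter medians lie between -0.31 and 0.35 and fall below the median of all sites in each ligand, whose values of 1.11 to 2.18 depend on the scale. Sites in 5' UTRs and coding sequence also have low medians, -0.21 and 0.02 with E2.

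The response was also compared across quartiles of mean value over all 6 libraries, to describe strong and weak sites. From the weakest to the strongest quartile, the median log2 ratio to Vehicle went from 1.19 to 2.43 with E2, 0.72 to 1.48 with fulvestrant and 0.81 to 1.68 with GDC-0927. The strongest quartile held the sites of TFF1, GREB1 and IGFBP4 described above. With 4OH-tamoxifen the values were 1.34 and 2.04, and with GNE-274 1.99 and 2.59, with the second quartile of GNE-274 at 1.96. Since 5 of the 6 libraries behind the mean value are ligand libraries, sites with higher ligand values fall in higher quartiles by construction, and these values do not separate strength from response.

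Against E2, the test compounds addressed how occupancy with each compound compared with that of the agonist at the same sites, and the doses differed, at 1 nM for E2 and 100 nM for each compound. TFF1 was 0.136 (0.123 to 0.1504) times E2 with fulvestrant, 0.240 (0.219 to 0.262) with GDC-0927, 0.308 (0.285 to 0.333) with 4OH-tamoxifen and 0.694 (0.651 to 0.739) with GNE-274. GREB1 was 0.237 (0.211 to 0.267) times E2 with fulvestrant and 0.444 (0.399 to 0.492) with GDC-0927, but 0.839 (0.772 to 0.911) with 4OH-tamoxifen and 1.18 (1.09 to 1.28) with GNE-274. RET was lower with all 4 compounds, from 0.168 (0.139 to 0.203) times E2 with fulvestrant to 0.401 (0.342 to 0.469) with GNE-274. CDK1 was 0.0964 (0.0727 to 0.126) times E2 with fulvestrant and 1.11 (0.981 to 1.27) with GNE-274, and ESR1 was 0.176 (0.151 to 0.204) and 1.06 (0.970 to 1.17) times E2. SERPINA1, a protease inhibitor, had a promoter site at 0.306 (0.226 to 0.410) times E2 with GNE-274 (chromosome 14, 94390704 to 94390974). The shift was -0.62 with fulvestrant, -0.52 with GDC-0927, -0.18 with 4OH-tamoxifen and 0.39 with GNE-274, and with equal totals it turned to 0.24, 0.16 and 0.22 for the first 3 and fell to 0.25 for GNE-274. Relative to the shift, TFF1 stood at -2.25, -1.54, -1.52 and -0.92 and RET at -1.94, -1.61, -1.60 and -1.71 in that order. With GNE-274, GREB1, CDK1 and ESR1 turned to -0.15, -0.24 and -0.30, and with 4OH-tamoxifen GREB1 stood at -0.08 and was above E2 with equal totals, so these directions depended on the scale.

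The estrogen-induced genes had a median log2 ratio to E2 of -1.60 with fulvestrant, where 25 of 32 were at least 2-fold lower, and the percentile was 0.01. With GDC-0927 the median was -0.999, 16 genes were at least 2-fold lower and the percentile was 1.09. With 4OH-tamoxifen and GNE-274 the medians were -0.30 and 0.01, at percentiles 70.7 and 10.1, and the latter moved to 0.26 with the mean of all sites per gene. Relative to the shift the 4 medians were -0.98, -0.48, -0.12 and -0.39 for fulvestrant, GDC-0927, 4OH-tamoxifen and GNE-274, so that of GNE-274 turned negative, and that of 4OH-tamoxifen lay above 0 with equal totals. Matched random lists had median log2 ratios to E2 of -0.84, -0.65, -0.37 and 0.20 in the same order, each also below the shift. The estrogen-repressed genes had medians of 0.14 with fulvestrant and 0.17 with GDC-0927, with 1 and 2 of 10 genes at least 2-fold higher and 0 lower. Their percentiles were 99.55 and 99.2, although within 10 kb of the gene body these were 97.2 and 70.4. The luminal factors had medians of -1.12 with fulvestrant and -0.96 with GDC-0927, at percentiles 16.1 and 8.64.

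Among the sites above the median mean value, an intergenic site assigned to LOC102723460 had one of the lowest ratios to E2 with fulvestrant, at 0.0584 (0.0468 to 0.0721) (chromosome 20, 48572271 to 48572516). XRCC3, a DNA repair gene, was assigned a site in an intron of KLC1 at 0.0748 (0.0614 to 0.0904) times E2 with 4OH-tamoxifen (chromosome 14, 103693422 to 103693796). An intergenic site of SMAD7, an inhibitor of TGF-beta signalling, was 0.108 (0.0689 to 0.161) times E2 with GDC-0927 (chromosome 18, 48996982 to 48997285), and one of CXXC5, a zinc finger protein, was 0.148 (0.107 to 0.2003) times E2 with GNE-274 (chromosome 5, 139644189 to 139644388). In the other direction, a site assigned to MBOAT1, an acyltransferase, was 13.0 (7.01 to 26.6) times E2 with GNE-274 (chromosome 6, 20291772 to 20291983, intron of LOC101928573). Sites at least 2-fold higher and lower than E2 numbered 756 and 10013 with fulvestrant, 889 and 8006 with GDC-0927, 2246 and 4823 with 4OH-tamoxifen and 7189 and 2154 with GNE-274. With equal medians they were 3478 and 4134, 2723 and 3234, 3035 and 3403, and 3895 and 3812. The exact binomial read test called 730 higher and 12298 lower with fulvestrant, 734 and 9668 with GDC-0927, 2441 and 7148 with 4OH-tamoxifen and 9759 and 3608 with GNE-274. Of the 16114 sites called with E2, 61.6% were also called with fulvestrant, 62.0% with GDC-0927, 72.2% with 4OH-tamoxifen and 81.3% with GNE-274. Calls drawn independently would have shared 6854, 6569, 8782 and 12141 sites, against 9924, 9985, 11631 and 13097 observed, and all calls share the pooled input. Each site of the union was called in at least 1 library, so such expectations, here and for other pairs, are not values for unrelated calls, and Vehicle shared 2588 sites with GNE-274 against 3325 expected.

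GDC-0927 and GNE-274 were compared at the same dose, 100 nM, and the same time, 45 min. TFF1 was 0.346 (0.314 to 0.380) times as high with GDC-0927 as with GNE-274 and GREB1 0.375 (0.338 to 0.416) times. CELSR2, a cadherin, had an intergenic site at 0.222 (0.183 to 0.267) (chromosome 1, 109246302 to 109246572), AREG, an EGF receptor ligand, one at 0.217 (0.165 to 0.283) (chromosome 4, 74579994 to 74580221), and the CDK1 site was at 0.234 (0.191 to 0.286). CTSD was nearer to equal at 0.744 (0.681 to 0.814), as was RARA at 0.565 (0.517 to 0.616). AHRR, the repressor of the aryl hydrocarbon receptor, was higher with GDC-0927 at 2.95 (2.098 to 4.23) (promoter, chromosome 5, 302158 to 302452), as was PSCA, a surface antigen, with 164 against 119 (intron, chromosome 8, 142676014 to 142676313). The shift was -0.92, and relative to it TFF1 stood at -0.61, GREB1 at -0.49, CELSR2 at -1.24, AREG at -1.26 and CDK1 at -1.16. RARA at 0.10 and CTSD at 0.50 turned to the other side, IGFBP4 stood at -0.02, and AHRR reached 2.47. The estrogen-induced genes had a median of -0.96 (-0.04 relative to the shift, percentile 19.4), and the cell cycle genes had 0.10 at the 99.9 percentile, with 9 of 10 above the shift. This was not particular to GDC-0927, since the cell cycle percentile against GNE-274 was 99.8 for fulvestrant and 100.0 for 4OH-tamoxifen, and that of GNE-274 against E2 was 1.62.

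At single sites, NCS1, a neuronal calcium sensor, had an intronic site at 6.63 (4.66 to 9.68) times the GNE-274 value (chromosome 9, 130187201 to 130187419). PTPRH, a receptor phosphatase, and DMPK, a muscle kinase, had promoter sites at 6.14 (4.17 to 9.35) (chromosome 19, 55207193 to 55207434) and 4.95 (3.79 to 6.54) (chromosome 19, 45781809 to 45782083). At the other end, intergenic sites of NPTX2, a neuronal pentraxin, and GLI2, a Hedgehog effector, were 0.0638 (0.0323 to 0.114) (chromosome 7, 98678005 to 98678303) and 0.0749 (0.0378 to 0.135) (chromosome 2, 121065115 to 121065360) times GNE-274. Promoters were 5 of the 10 highest sites and 0 of the 10 lowest. At least 2-fold higher with GDC-0927 were 567 sites and 13877 were lower, against 3173 and 3634 with equal medians, and the exact binomial read test called 894 higher and 16406 lower. Called with both were 10540 sites, against 9179 expected from independent calls.

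The 4 test compounds were also compared with each other at their common dose and time. The TEX14 site, in an intron of a germ cell gene, had 3857 with 4OH-tamoxifen and 5493 with GNE-274, against 444 with fulvestrant and 1003 with GDC-0927 (chromosome 17, 58639715 to 58639992). PARD6B, a cell polarity gene, showed the same order at an intergenic site, with 5083 and 6304 against 971 and 1683 (chromosome 20, 50727487 to 50727754). The reverse held at the intergenic site assigned to BCAS4, a gene in a breast cancer amplicon, with 3395 for fulvestrant and 3235 for GDC-0927 against 1247 for 4OH-tamoxifen and 1885 for GNE-274 (chromosome 20, 50764178 to 50764439). That site lies 30.5 kb from the BCAS4 gene body. Relative to the shift of GDC-0927 against GNE-274, TEX14 stood at -1.53, PARD6B at -0.98 and BCAS4 at 1.70. The 2 directions were then counted among sites above the median mean value, after the values were seen. At least 2-fold higher with both 4OH-tamoxifen and GNE-274 than with both other compounds were 1881 sites, and 91 went the other way. With equal medians these counts were 706 and 760. Across sites, the Pearson correlation was 0.917 between fulvestrant and GDC-0927 and 0.907 between 4OH-tamoxifen and GNE-274. The Spearman values of these pairs were 0.904 and 0.889. For the other pairs of compounds Pearson's r lay between 0.786 and 0.822, and sites are not independent replicates. E2 had 0.855 with GDC-0927, 0.833 with 4OH-tamoxifen, 0.814 with fulvestrant and 0.808 with GNE-274. Vehicle had 0.643 with GDC-0927 and 0.628 with fulvestrant, against 0.505 with 4OH-tamoxifen and 0.484 with GNE-274. The log2 ratio of GDC-0927 to GNE-274 and that of fulvestrant to 4OH-tamoxifen, which share no library, had a correlation of 0.700 over the 14943 sites above the median mean value. For GDC-0927 to fulvestrant against GNE-274 to 4OH-tamoxifen it was -0.0385.

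The median log2 ratio between fulvestrant and GDC-0927 was -0.14, with 700 sites at least 2-fold higher and 2047 lower, and between 4OH-tamoxifen and GNE-274 it was -0.57, with 248 and 5616. With equal medians those splits were 1228 and 1248, and 1168 and 1303. Fulvestrant and 4OH-tamoxifen differed more, with 3610 sites higher and 3778 lower at equal medians, as did fulvestrant and GNE-274 with 3384 and 3723 and 4OH-tamoxifen and GDC-0927 with 3186 and 3149. On the deposited scale these 3 splits were 1295 and 7516, 327 and 15450, and 5985 and 1723, at shifts of -0.45, -1.03 and 0.36. The estrogen-induced genes had a median of -0.96 for fulvestrant against 4OH-tamoxifen (percentile 0.170) and -1.62 against GNE-274 (0.0600), -0.51 and -0.59 relative to the shift. Against GDC-0927 the fulvestrant median of this list was -0.56 (percentile 0.210), or -0.42 relative to the shift with 26 of 32 genes below it, whereas 4OH-tamoxifen against GNE-274 was at the 86.9 percentile. Matched random lists for fulvestrant against GDC-0927 had a median of -0.29, also below the shift of -0.14. Calls were shared at 9920 sites between fulvestrant and GDC-0927, against 5182 expected from independent calls, and at 14441 between 4OH-tamoxifen and GNE-274, against 12272.

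**Figure D4:**
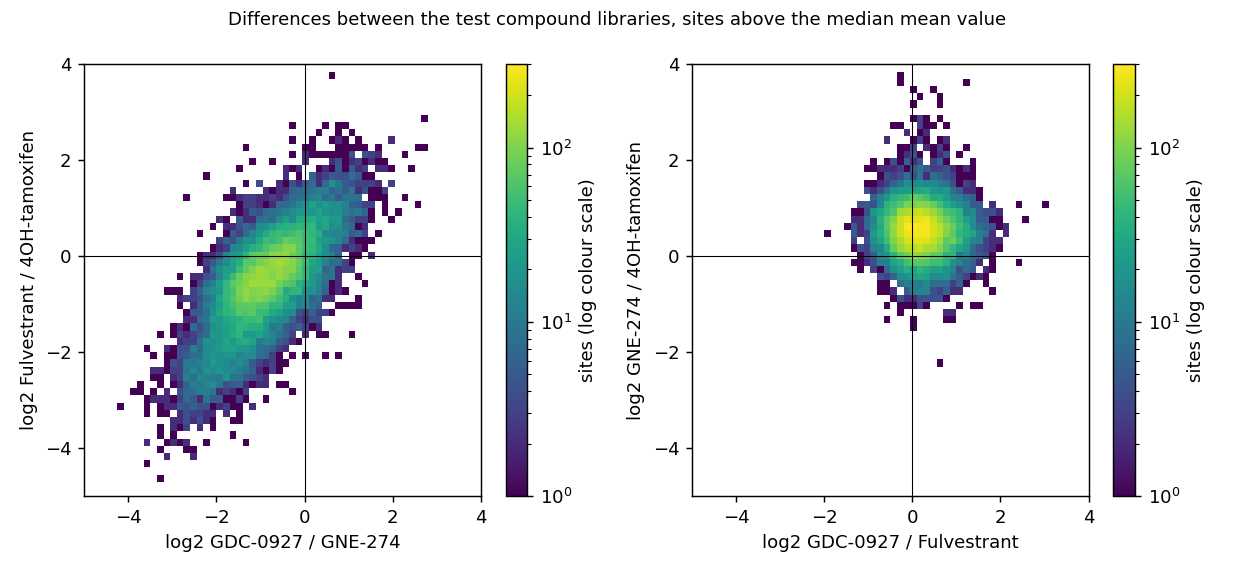
Sites above the median mean value by log2 ratio of normalised counts, with the number of sites per bin in colour on a log scale; left, GDC-0927 to GNE-274 (x) against fulvestrant to 4OH-tamoxifen (y), right, GDC-0927 to fulvestrant (x) against GNE-274 to 4OH-tamoxifen (y). The left cloud is elongated, with a correlation of 0.700, and the right one is not, at -0.0385; the position of each cloud on both axes depends on the scale between libraries.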

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

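The tests chosen only after the data were seen were the exact binomial read test, the gene lists limited to sites within 10 kb of the gene body, and the ligand ratios without promoter sites, while the comparisons, the gene lists and the other alternatives were set before the data were examined. Depth limits the sites with few reads, since the median site had 12 reads in Vehicle and 195 sites had none there. With 1 library per group no library could be left out, and no paired analysis was possible because each condition had a single library. Not run were a 50% reciprocal overlap (the sites share 1 set of coordinates), a stricter peak threshold (calls are 0 or 1), a limit of distance to the transcription start or a wider promoter (no strand came with the gene table), and estrogen response element content (no reference genome came with the series). With a pseudocount of 0.1, and without chromosomes 1, 17 and 20, the shares of sites higher and lower stayed within 1.5 times their value in all 10 comparisons tested. Of the list percentiles in 10 comparisons, all but 3 kept their side of the limits under median scaling (117 did), all but 9 with the mean of all sites per gene (111 did) and all but 8 within 10 kb of the gene body (102 did). Within 10 kb a list needed at least 3 genes, so fewer percentiles were placed there. Over all 15 comparisons 19 of 180 percentiles lay outside the limits, so most only stayed inside. Percentiles that moved from outside to inside numbered 1, 3 and 5 in the same order. Except where scaling or a limit on sites shows it by construction, the cause of the values that follow was not tested.

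With libraries scaled to equal medians, the percent of sites at least 2-fold higher and lower against Vehicle was 26.2 and 19.7 for E2, 22.5 and 16.1 for fulvestrant, 25.5 and 18.4 for 4OH-tamoxifen, 21.9 and 15.8 for GDC-0927 and 27.7 and 19.6 for GNE-274. Against E2 it was 11.6 and 13.8 for fulvestrant, 9.11 and 10.8 for GDC-0927 and 13.0 and 12.8 for GNE-274, and for GDC-0927 against GNE-274 it was 10.6 and 12.2. The median log2 ratio of fulvestrant to E2 turned to 0.0449. The highest minus the lowest quartile of mean value was 1.10 for E2, 0.66 for fulvestrant, 0.58 for 4OH-tamoxifen, 0.77 for GDC-0927 and 0.43 for GNE-274. The percentile of the estrogen-repressed list with E2 was 2.71, of the liver list for 4OH-tamoxifen against E2 2.31, and of the T cell list for fulvestrant against E2 97.9.

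With equal totals, the percent of sites higher and lower against Vehicle was 20.95 and 23.6 for E2, 22.2 and 16.4 for fulvestrant, 25.9 and 18.2 for 4OH-tamoxifen, 20.4 and 16.1 for GDC-0927 and 27.2 and 19.8 for GNE-274. Against E2 it was 17.4 and 10.2 for fulvestrant, 16.1 and 7.63 for 4OH-tamoxifen and 13.5 and 7.14 for GDC-0927, and for GDC-0927 against GNE-274 it was 10.3 and 12.5. The median log2 ratio reversed to -0.0248 for E2 against Vehicle and to 0.245, 0.223 and 0.161 for fulvestrant, 4OH-tamoxifen and GDC-0927 against E2. The median normalised count was 28.6 in Vehicle, 24.5 with E2, 28.3 with fulvestrant, 28.9 with 4OH-tamoxifen, 28.0 with GDC-0927 and 28.3 with GNE-274.

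Among sites above the median mean value, the percent lower than Vehicle was 0.903 for E2, 3.26 for fulvestrant, 2.56 for 4OH-tamoxifen, 1.65 for GDC-0927 and 0.582 for GNE-274. The percent higher than E2 was 0.903, 3.25, 1.04 and 16.0 for fulvestrant, 4OH-tamoxifen, GDC-0927 and GNE-274. Spearman correlations across these sites were 0.876 for fulvestrant with GDC-0927, 0.879 for 4OH-tamoxifen with GNE-274, 0.585 and 0.588 for fulvestrant with 4OH-tamoxifen and GNE-274, and 0.655 and 0.642 for GDC-0927 with 4OH-tamoxifen and GNE-274.

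With a limit of 1.5-fold, the percent lower than Vehicle was 6.53 for E2 and 5.68 for GNE-274. Higher and lower than E2 were 7.0002 and 51.9 for fulvestrant, 17.1 and 30.7 for 4OH-tamoxifen, 7.81 and 46.7 for GDC-0927 and 41.5 and 14.8 for GNE-274, and 4.77 were higher with GDC-0927 than with GNE-274. Without promoter sites the percent lower than Vehicle was 1.71, 2.95, 2.39, 2.48 and 1.72 for E2, fulvestrant, 4OH-tamoxifen, GDC-0927 and GNE-274. A pseudocount of 5 gave 1.27, 4.68 and 1.40 percent higher than E2 for fulvestrant, 4OH-tamoxifen and GDC-0927. The exact binomial read test called 12.1 percent lower with GNE-274 than with E2, and 2.99 percent higher with GDC-0927 than with GNE-274.

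With the mean of all sites per gene, the percentile of the estrogen-induced list was 95.7 for E2 against Vehicle and 0.260 for GNE-274 against E2. For the estrogen-repressed list it was 7.92 for E2 against Vehicle and 97.0 for GDC-0927 against E2. The basal list with GNE-274 against Vehicle was at 98.0, the liver list for 4OH-tamoxifen against E2 at 1.36, the T cell list for fulvestrant against E2 at 98.0, and the housekeeping list at 2.25 and 1.87 for fulvestrant and 4OH-tamoxifen against Vehicle. Within 10 kb of the gene body, the estrogen-induced list was at 99.3 for 4OH-tamoxifen and 98.0 for GNE-274 against Vehicle. The estrogen-repressed list was at 9.15 for E2 against Vehicle and at 97.2 and 70.4 for fulvestrant and GDC-0927 against E2. The cell cycle list was at 7.99 for E2 and 7.43 for GNE-274 against Vehicle, and the AP-1 list with 4OH-tamoxifen against Vehicle reversed to 2.06.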

Other observations

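The tests chosen only after the result was seen were the correlation of ratios that share no library with its simulation and its value away from promoters, the level of promoter sites, the E2 ratio of the strongest sites inside the segments of chromosomes 20 and 17, and the counts limited to strong sites. The AP-1 and immediate early genes (10 of 12 with a site) had a median log2 ratio to Vehicle of 2.13 with E2, 2.25 with 4OH-tamoxifen and 0.57 with fulvestrant, and the 4OH-tamoxifen percentile of 82.5 turned to 2.06 when only sites within 10 kb of the gene body were used. For fulvestrant against 4OH-tamoxifen their median was -1.61, at the 0.190 percentile, or -1.15 relative to the shift. FOSL2, an AP-1 subunit, had an intergenic site at 0.209 (0.168 to 0.257) times the 4OH-tamoxifen value with fulvestrant (chromosome 2, 28377275 to 28377527), and FOS one at 0.284 (0.240 to 0.335) times (chromosome 14, 75260096 to 75260364). The list went both ways, with 6 genes below the shift and 4 above it, among them IER2, chosen after its values were seen, at 3.78 (2.67 to 5.47) times (chromosome 19, 13162715 to 13162941, intergenic). Among nuclear receptor coregulators (8 of 12 with a site) the median with E2 was 1.29, at the 13.0 percentile, and NRIP1, a corepressor induced by estrogen, was 8.14 (6.81 to 9.80) times Vehicle (chromosome 21, 15210332 to 15210575, intergenic). Genes of the aryl hydrocarbon receptor response (6 of 8 with a site) had a median of 2.45 with E2 (71.9 percentile), with NQO1, a quinone reductase, at 6.50 (4.12 to 10.7) times Vehicle (chromosome 16, 69723855 to 69724071, intron).

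Genes of other lineages also had ER sites. With E2 the basal and mesenchymal genes (4 of 10 with a site) had a median log2 ratio to Vehicle of 2.79, at the 96.4 percentile, and the liver genes (5 of 10) had 2.23, at the 74.6 percentile. Against E2 the liver genes stood at -1.61 with GDC-0927 (0.275 percentile, 0 at least 2-fold higher and 3 lower), -0.65 with GNE-274 (1.00 percentile, 1 higher and 2 lower) and -1.29 with fulvestrant (6.12 percentile, 0 higher and 3 lower), and with GNE-274 the 5 genes went both ways. The T cell genes (3 of 10) and the neural genes (6 of 10) had medians of 1.203 and 1.70 with E2, at the 33.9 and 69.7 percentiles. The housekeeping genes (6 of 10) had 0.31 with E2 and -0.01 with 4OH-tamoxifen, at the 4.60 and 3.33 percentiles. Promoter sites as a class had medians of 0.20 and -0.02, and the random lists were not matched on location. Of 180 percentiles over 12 lists and 15 comparisons, 19 lay outside the central 95%, where 9 would by chance alone, and no expression was measured at any of these genes.

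Promoter sites had lower ligand ratios than other sites, with a gap in median log2 E2 to Vehicle ratio of 1.68 as deposited. Other sites here pool all remaining classes, of which 5' UTR and coding sites had low medians too (-0.21 and 0.02 with E2). A planned test of scaling was dropped, since 1 factor per library leaves such a gap as it is by construction. Weaker signal at promoters could not be tested apart from the gap itself. The median value over all libraries was 0.995 (0.957 to 1.03, bootstrap over sites) times that of other sites, but this mean includes the ligand libraries. The medians were 31.4 at promoters against 10.1 at other sites in Vehicle, and 35.1 against 37.8 with E2. A planned matching on that mean, with a gap of 1.82, was dropped because the mean includes the ligand libraries. Choice of promoter sites by the Vehicle call was argued against as the whole cause by a gap of 2.21 (2.13 to 2.29) among the 2040 sites called in all 6 libraries, although the gap of 0.843 at sites not called in Vehicle leaves open that the call may account for part of it. Signal at open promoters that is independent of ER stays open, since the files used here hold no input column, and no biological explanation was tested.

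Across sites fulvestrant correlated most with GDC-0927 and 4OH-tamoxifen with GNE-274 among the compounds, although the estrogen-induced genes lay at the 0.210 percentile for fulvestrant against GDC-0927, and lower read depth was argued against as the cause: after thinning to 687472 reads per library, the correlation of fulvestrant with GDC-0927 exceeded that of GDC-0927 with GNE-274 by 0.104. A common set of sites bound at 1 yield per library with independent library error was argued against: the ratio of GDC-0927 to GNE-274 and that of fulvestrant to 4OH-tamoxifen, which share no library, had a correlation of 0.700 (0.691 to 0.709). The highest value in 100 simulations with the yields of the libraries was 0.0218. Their errors were independent, so a value near 0 was set by design and adds no support. Background that differs between libraries was not simulated and stays open. Fulvestrant and GDC-0927 also correlated more with Vehicle (0.628 and 0.643) than 4OH-tamoxifen and GNE-274 did (0.505 and 0.484). At the 4744 sites of the highest quartile that were neither promoters nor called in Vehicle the correlation was 0.797 (0.786 to 0.809). A planned count of sites at least 1.5 times higher with fulvestrant and GDC-0927, 532 against at most 711 simulated (313 and 184 in a first run on stronger sites alone, where the correlation difference was 0.166), was dropped because its simulation assumed equal yields. The reverse count, higher with 4OH-tamoxifen and GNE-274, was 8433, and with equal medians the 2 counts were 2854 and 2885. Handling shared within each pair of libraries stays open, and whether the compounds differ in biology was not tested with 1 library each.

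The strongest sites clustered on the long arm of chromosome 20 and distal 17, with 81 of the 298 sites in the top 1 percent (27.2%) in segments that hold 4.48% of sites, among them one assigned to CYP24A1, a vitamin D hydroxylase, at 12.8 (11.9 to 13.7) times Vehicle with E2 (chromosome 20, 54123748 to 54124007, intergenic). That site lies 19.5 kb from the CYP24A1 gene body. The segments ran from 44 Mb on chromosome 20 and from 52 Mb on chromosome 17. Copy gain in MCF-7 may contribute, since promoter sites inside the segments had a median value 1.77 (1.56 to 2.05) times that of those outside, and other sites 2.11 (1.95 to 2.29) times. Both values come from the libraries in which the cluster was seen, so they cannot separate copy gain from higher binding in these segments. Whether copy gain alone is enough for the strongest sites stays open, since the median log2 E2 to Vehicle ratio of the sites in the top 1 percent was -0.39 (-0.74 to 0.21) inside minus outside, an interval too wide to decide. A planned difference over all other than promoter sites was -0.43 (-0.51 to -0.32), outside the limits that were planned for copy gain alone. It was set aside after it was seen, on the ground that extra copies also lift background, which was not tested. These sites were 3.0 times as high inside as outside in Vehicle against 2.12 times with E2, which restates that difference. A first run started the chromosome 20 segment at 33 Mb in place of the planned 44 Mb and gave 1.61 (1.41 to 1.84) for promoters and -0.37 (-0.47 to -0.30) for that difference, and no copy number was measured and no biological explanation tested.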
